A study of Mus musculus with 26 samples.

How the data were processed

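Expression was measured on Illumina BeadChip arrays in 26 samples of total RNA, 2 technical arrays (a and b) for each of 13 mouse cell lines. Per the labels, all lines share the OG2 strain background, and the lines fall into 6 groups: germline stem cells (GSC, 2 lines), induced pluripotent stem cells made from GSCs (iPSC, 4 lines), germline-derived pluripotent stem cells (gPSC, 4 lines), embryonic stem cells (ESC, 1 line), fibroblasts (1 line) and induced pluripotent stem cells made from fibroblasts (Fib-iPSC, 1 line). The design text of the series counts 12 lines and leaves the fibroblasts out, while the labels give 13. RNA was amplified to biotinylated cRNA before hybridization.

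The submitters' processing notes name BeadStudio 3.2 and lumi, without saying what each did. The deposited table gives for each array the intensity of 25697 probes, which its medians and maxima show to be neither normalized nor background-subtracted. Beside each intensity the deposited table gives a detection p-value, the share of negative control probes at least as bright as the probe; the steps between its values imply 798 negative controls. The authors' own processed values are on a log2 scale and were quantile normalized across the 26 arrays after a background adjustment whose method is not stated; every array of that table has the same sorted values. Median intensity per array ran from 89.17 to 143.2, and 12097 to 13808 probes per array had a detection p-value under 0.05. For arrays, the number of arrays and lines limits the precision.

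Intensities were background-corrected, quantile normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16. The 2 arrays of a line were averaged, so that a line is the unit of every test and the p-values measure the spread between lines, not between arrays. Probes with a detection p under 0.05 on both arrays of at least 1 line were kept (15917 of 25697, 61.9%). Gene names come from the platform's probe table: 23978 probes name 1 gene, 0 name several and 1719 name none, and 969 of the unnamed ones passed the detection filter and were left out. Of the named probes, 23962 have their gene in the RefSeq table of assembly GRCm38.p6, which was used for names only. For a gene with several probes (3830 genes), the probe with the highest mean over the lines was used, which left 10660 genes. The lowest signal that counted as detected on an array, its floor, had a median of 4.63 on this log2 scale and ran from 4.56 to 4.81.

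A linear model with 1 mean per group was fitted to all 13 lines with limma, which leaves 7 residual degrees of freedom among lines and 9.29 in the moderated test. Groups of 1 line have no spread of their own and are assumed to vary like the other groups. The comparisons were iPSC versus GSC, gPSC versus GSC, iPSC versus gPSC, iPSC versus ESC, gPSC versus ESC and GSC versus ESC. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 (two-sided, over the 10660 genes) with at least a 2-fold difference. Fib-iPSC against ESC and against fibroblast compare 1 line with 1 line and have no test; list medians there were placed among 10000 random lists matched in size and expression level. Where every array of the lower group lacked detection for all probes of a gene, the fold was computed against the floors of those arrays and is written as a lower bound ("at least"). Where only some of these arrays detected it, the measured difference is given with their number. For these genes a difference with the lower group's values raised to the floor of their array was chosen after the data were seen.

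A germline signature was defined as the genes at least 4-fold higher in GSC than in ESC and called, a fibroblast signature as the genes at least 4-fold higher in fibroblast than in ESC and detected on both fibroblast arrays. The retained share of a signature in a line is its mean log2 difference to ESC over the signature genes, in percent of the source cell's own mean difference; 0% is the ESC level and 100% the source level. Distances between lines are root mean square log2 differences over all genes. Differences of such values between the iPSC and gPSC lines were tested with two-sided exact permutation tests over the 70 assignments of the 8 lines, whose smallest p is 0.029, adjusted over the 8 measures tested.

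The 15 gene lists, written from general knowledge, were pluripotency network, spermatogonial stem cell and germline, meiosis and later spermatogenesis, fibroblast and mesenchymal (which also covers feeder cells), epithelial adhesion, paternally expressed imprinted, maternally expressed imprinted, epiblast priming and germ layer, two-cell-like, DNA methylation and chromatin, glycolysis, oxidative phosphorylation, p53 targets, sex-linked and testis somatic cells. They were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 15 lists. Camera asks whether a list moved more than other genes; fry asks whether its genes moved, on balance, one way. Named genes are the 10 largest rises and falls among called genes whose lines do not overlap and that were detected on every array of the higher group; of each list the 2 called members with the largest rise and fall, or the 2 with the smallest p where none was called; and Pou5f1, Nanog, Sox2, Klf4, Myc, Zbtb16, Ddx4, Dazl, H19, Igf2, Meg3 and Snrpn where measured. For comparisons of single lines the 10 largest differences each way were eligible. The samples' groups, tests, lists, naming rule and most alternatives were fixed before the data were examined; genes outside the rule are marked as chosen after their values were seen.

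Alternatives were log2 quantile normalization without background correction (offset 16), the authors' processed values, no detection filter and a stricter one (detection p under 0.01 on all arrays of a group), all probes, the 26 arrays with line as a random block, only the groups compared, limma with trend and robust options, no fold threshold, each ESC array alone, other signature definitions, medians, a correlation distance and leaving out each line in turn. Line number as a block was run; slide as a block was not run, since the files give no slides. Alternatives chosen after the data were seen were the b arrays alone, a term for the array set (on the 26 arrays with line as a random block), leaving out lines from the list tests, and a separate GSC line for each comparison in the overlap of calls. The procedure was tested on simulated data with 200 of 10660 genes changed: of the 4-fold changes it recovered 92% for iPSC versus GSC, 92% for gPSC versus GSC, 96% for iPSC versus gPSC, 88% for iPSC versus ESC, 90% for gPSC versus ESC and 76% for GSC versus ESC. Of the 2-fold changes it recovered 24%, 44%, 52%, 20%, 26% and 26% in the same order, with 10, 6, 1, 8, 5 and 10 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.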

Results

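Genome-wide transcript levels were compared between mouse germline stem cells (GSC), which are unipotent cells of the male germ line that can be kept in culture, and pluripotent lines obtained from them by different routes. The iPSC lines were reprogrammed from GSCs. The gPSC lines are also pluripotent and germline-derived. Published protocols obtain such lines by culture without introduced factors, although the labels do not state the route used. An ESC line, a fibroblast line and an iPSC line made from fibroblasts (Fib-iPSC) served as references. The title of the series puts the question whether reprogramming by transcription factors leaves a trace of the source cell. The comparisons therefore ask what changed on the way from GSC, whether the iPSC and gPSC lines differ, and how far each lies from ESC. Each of the 13 lines (2 GSC, 4 iPSC, 4 gPSC and 1 of each reference) was measured on 2 arrays, which correlated at r = 0.99447 to 0.99697 across genes.

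The arrays themselves fell into sets. The a arrays of the GSC, gPSC, ESC and Fib-iPSC lines had median intensities of 100.1 to 102.9, against 89.48 to 93.96 on the b arrays of the same lines, 89.17 to 93.24 on both arrays of the iPSC lines, and 134.4 and 143.2 on the fibroblast arrays. The probe of Iapp, the islet amyloid polypeptide gene (chosen after its values were seen), followed these sets: it read 122.3 to 155.5 on the a arrays, 84.4 to 92.85 on the b arrays and 81.82 to 90.32 on the iPSC arrays. On the b arrays alone, 1 array per line, limma called 2415 genes for iPSC versus GSC, 2286 for gPSC versus GSC, 0 for iPSC versus gPSC, 17 for iPSC versus ESC, 20 for gPSC versus ESC and 2148 for GSC versus ESC.

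The lines separated first by cell state. The first 2 principal components held 42.6% and 30.7% of the variance and set the GSC lines and the fibroblast line apart from all pluripotent lines, while the third (13.9%) ran through the pluripotent lines from iPSC 3 to gPSC 1. Root mean square distance to ESC, over 10660 genes on the log2 scale, was 0.455 ± 0.110 for iPSC (SD, n = 4) and 0.517 ± 0.131 for gPSC (SD, n = 4), against 1.08 ± 0.017 for GSC (SD, n = 2). The iPSC and gPSC lines did not differ in distance to ESC (difference -0.0623, two-sided exact permutation p = 0.486, n = 4 and 4) or to GSC (difference 0.017, exact permutation p = 0.657), and after adjustment over the 8 measures these were 0.685 and 0.714. Without gPSC 2 the difference in distance to GSC turned to -0.00818. When single lines were left out, the difference in distance to ESC ran from -0.112 (without iPSC 3) to -0.00363 (without gPSC 1).

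**Figure D1:**
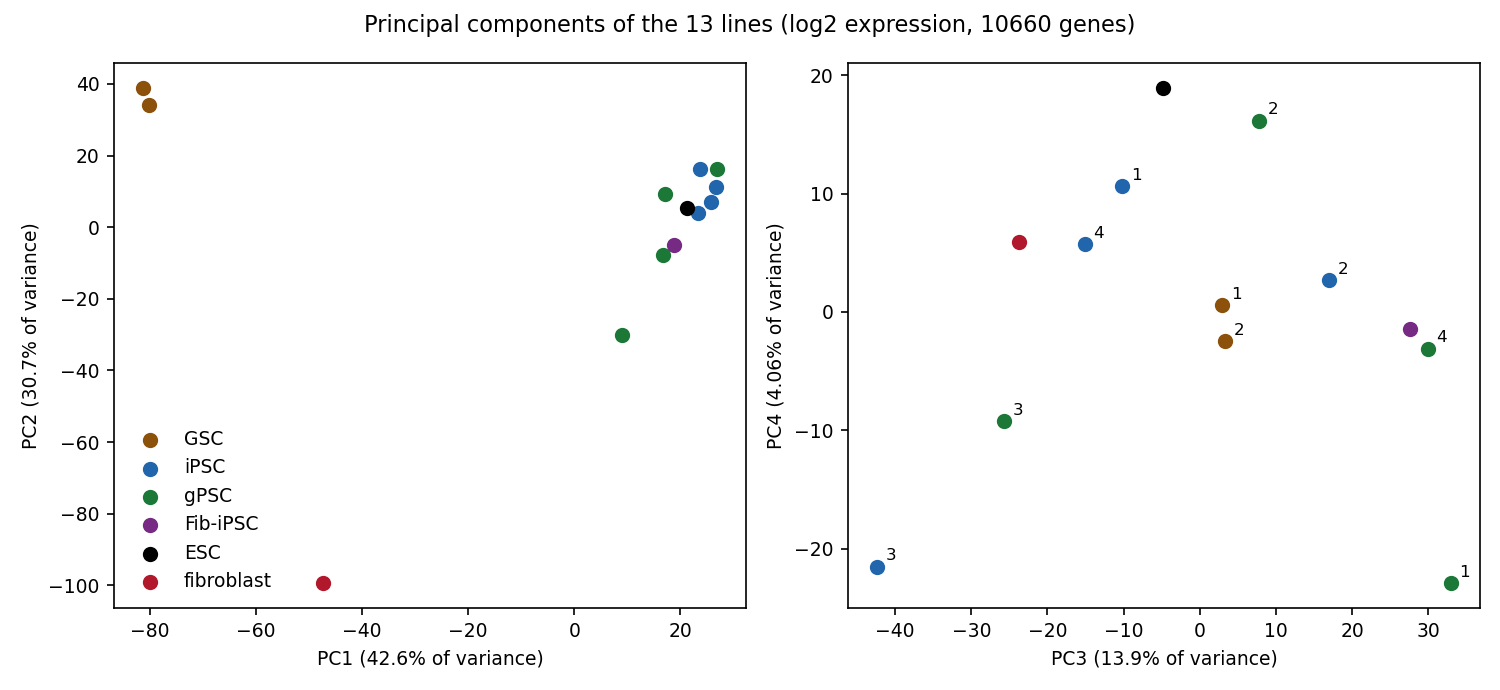
Principal components of log2 expression in 13 lines, PC1 against PC2 (left) and PC3 against PC4 (right), each axis with its share of the variance and each point a line, coloured by group. The GSC lines sit at -81.22 and -80.13 on PC1 while all pluripotent lines lie between 8.92 and 26.93; on PC3, iPSC 3 (-42.38) and gPSC 1 (32.99) are the extremes.

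In the iPSC lines the pluripotency network was switched on relative to GSC. Nanog, a core pluripotency transcription factor, rose by a log2 difference of 7.27 ± 0.31 (SE, 4 lines against 2, adjusted p = 4.35e-07), Sox2 by 4.17 ± 0.29 and Pou5f1, which GSCs already expressed at a log2 level of 8.84, by 3.00 ± 0.40. The GSC lines differed in Pou5f1 (9.74 and 7.94), so that its rise ran from 2.10 to 3.90 when single lines were left out. Dnmt3l, the cofactor of de novo DNA methylation, rose by 6.81 ± 0.34, and L1td1, an RNA-binding protein of pluripotent cells, by 6.21 ± 0.32. Nanog and L1td1 were detected on 1 of 4 GSC arrays and Sox2 on 2, so these sizes lean on signals near background. With GSC values raised to the floor of their array they were 7.14, 6.16 and 4.15. Of the 29 measured genes of the pluripotency network, 21 rose, 1 fell and 7 were not called. Adjusted over the list alone, 22 and 1 passed. Stat3 was the one that fell (-1.68 ± 0.29). The list moved up against all other genes (camera adjusted p = 5.65e-12) and also with an estimated correlation (adjusted p = 0.0328). Without gPSC 1 in the fit that value was adjusted p = 0.0573.

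The germline programme went the other way. Of 34 spermatogonial and germline genes, 27 fell, 2 rose and 5 were not called (28 and 2 adjusted over the list alone; camera adjusted p = 9.21e-11, but adjusted p = 0.106 with an estimated correlation). Sohlh1, a transcription factor of differentiating spermatogonia, fell by 5.90 ± 0.33, Tktl1, a transketolase-like gene, by 5.13 ± 0.39, and the RNA helicase gene Ddx4 by 2.47 ± 0.45. Egr4, a transcription factor gene, fell most of all named genes (-7.79 ± 0.65), followed by Mageb4 (-6.53 ± 0.71). Of the 8 iPSC arrays, Tktl1 was detected on 3 (-5.05 with values raised to the floor), Sohlh1 and Egr4 on 6 and Mageb4 on 7. Upp1 (3.57 ± 0.55) and Etv5 (2.02 ± 0.41), listed as germline genes, rose. Dazl, an RNA-binding regulator of germ cells, was lower by -4.48 ± 1.41 (adjusted p = 0.0281), a call that ended without GSC 1, GSC 2, iPSC 1, iPSC 2 or iPSC 4 (adjusted p up to 0.129). The line iPSC 3 stood apart at 10.8 against 6.07 to 6.71 in the other iPSC lines. Taf7l, a testis-specific TFIID subunit, behaved alike: it fell (-4.97 ± 1.12), but was at 10 in iPSC 3 against 5.69 to 6 in the others.

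Of 19 glycolysis genes 14 rose and 0 fell (15 adjusted over the list alone), among them Pfkl, a subunit of phosphofructokinase (4.14 ± 0.53), and the glucose transporter gene Slc2a3 (3.40 ± 0.41). Camera gave adjusted p = 3.52e-06, but adjusted p = 0.622 with an estimated correlation. Of 26 oxidative phosphorylation genes only Ndufb5 was called (1.10 ± 0.18; 0.97 and no longer called without iPSC 4), and camera did not call the list (13 above and 13 below 0, adjusted p = 0.386). Of 16 p53 target genes 9 rose and 0 fell, led by the pro-apoptotic gene Bbc3 (3.60 ± 0.24) and Zmat3 (3.56 ± 0.19). Camera gave adjusted p = 2.32e-05, and adjusted p = 0.135 with an estimated correlation.

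Epithelial and early-embryonic genes also rose in part. Cdh1, which encodes E-cadherin, rose by 4.89 ± 0.18 and the tight junction gene Cldn4 by 6.21 ± 0.39. In this list 8 of 17 epithelial genes rose and Ocln fell (-1.36 ± 0.14; list camera adjusted p = 0.0156, adjusted p = 0.665 with an estimated correlation). Of 11 genes of the two-cell-like state, 6 rose, including Zscan4c (at least 39-fold higher) and Tcstv3 (at least 17.7-fold higher), and Piwil2, a piRNA pathway gene that the germline list also holds, fell (-3.48 ± 0.55). Camera gave adjusted p = 0.0126, and adjusted p = 0.657 with an estimated correlation. Otx2, a transcription factor of the primed epiblast, was at least 35-fold higher. Of 23 priming and germ layer genes 4 were called higher and 2 lower (camera adjusted p = 0.386). Of 23 DNA methylation and chromatin genes 6 were called higher and 2 lower (camera adjusted p = 0.0849), with Kdm4c, a histone demethylase gene, at 3.18 ± 0.36 and Bmi1, a Polycomb gene, at -1.63 ± 0.25. Cldn4 was detected on 3 of 4 GSC arrays, Ocln on 3 of 8 iPSC arrays (-1.26 with values raised to the floor) and Bmi1 on 7.

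Imprinted genes changed in both directions. Among 15 paternally expressed genes, 4 rose and 4 fell (camera adjusted p = 0.885): Snrpn rose by 2.92 ± 0.21 and Impact by 2.54 ± 0.17, while Inpp5f fell (-2.74 ± 0.24) and Ndn fell (-2.30 ± 0.31). Among 12 maternally expressed genes 2 were called higher and 3 lower (camera adjusted p = 0.885). Cdkn1c, an inhibitor of cyclin-dependent kinases, was lower by -2.93 ± 0.75, a call that ended without either GSC line (adjusted p up to 0.0817). The mesenchymal list had 4 of 33 genes called higher and 1 lower (camera adjusted p = 0.598), with the matricellular gene Ccn2 at 4.19 ± 0.22. Meiosis had 1 of 17 higher and 2 lower (0.135), with Sycp1, a synaptonemal complex gene, at -2.31 ± 0.40. Sex-linked genes had 0 of 4 higher and 1 lower (0.362), Kdm5d on the Y chromosome at -1.56 ± 0.22. Testis somatic cells had 2 of 9 higher and 1 lower (0.535), with Wt1 at -4.07 ± 0.44 and Rhox5, a homeobox gene that pluripotent cells also express, at 6.90 ± 0.63. Sycp1 was detected on 3 of 8 iPSC arrays, Kdm5d on 6 and Wt1 on 7, and Rhox5 on 3 of 4 GSC arrays. With values raised to the floor Sycp1 was at -2.21 and Kdm5d at -1.47.

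Across all genes, limma called 2432 of 10660 for iPSC versus GSC, 1188 higher and 1244 lower in iPSC. The lysosomal membrane gene Laptm5 was at least 94.1-fold higher and the secreted protein gene Wfdc2 at least 142-fold higher, and Radx, a DNA replication gene, was at least 23.4-fold lower. Klf4, one of the classical reprogramming factors, was barely past the threshold (1.09 ± 0.33, adjusted p = 0.0244), and its call ended without GSC 1, GSC 2, iPSC 1 or iPSC 4 (log2 difference down to 0.90, adjusted p up to 0.138). Igf2 (-0.17 ± 0.92, adjusted p = 0.906, turned to as much as 0.11 without GSC 2 or iPSC 2) and Myc (0.08 ± 0.12, adjusted p = 0.645) were not called; Myc was detected on 0 GSC arrays and 1 iPSC array. With log2 quantile normalization without background correction, 1023 genes were called, 1021 of them among the 2432 and in the same direction.

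**Figure D2:**
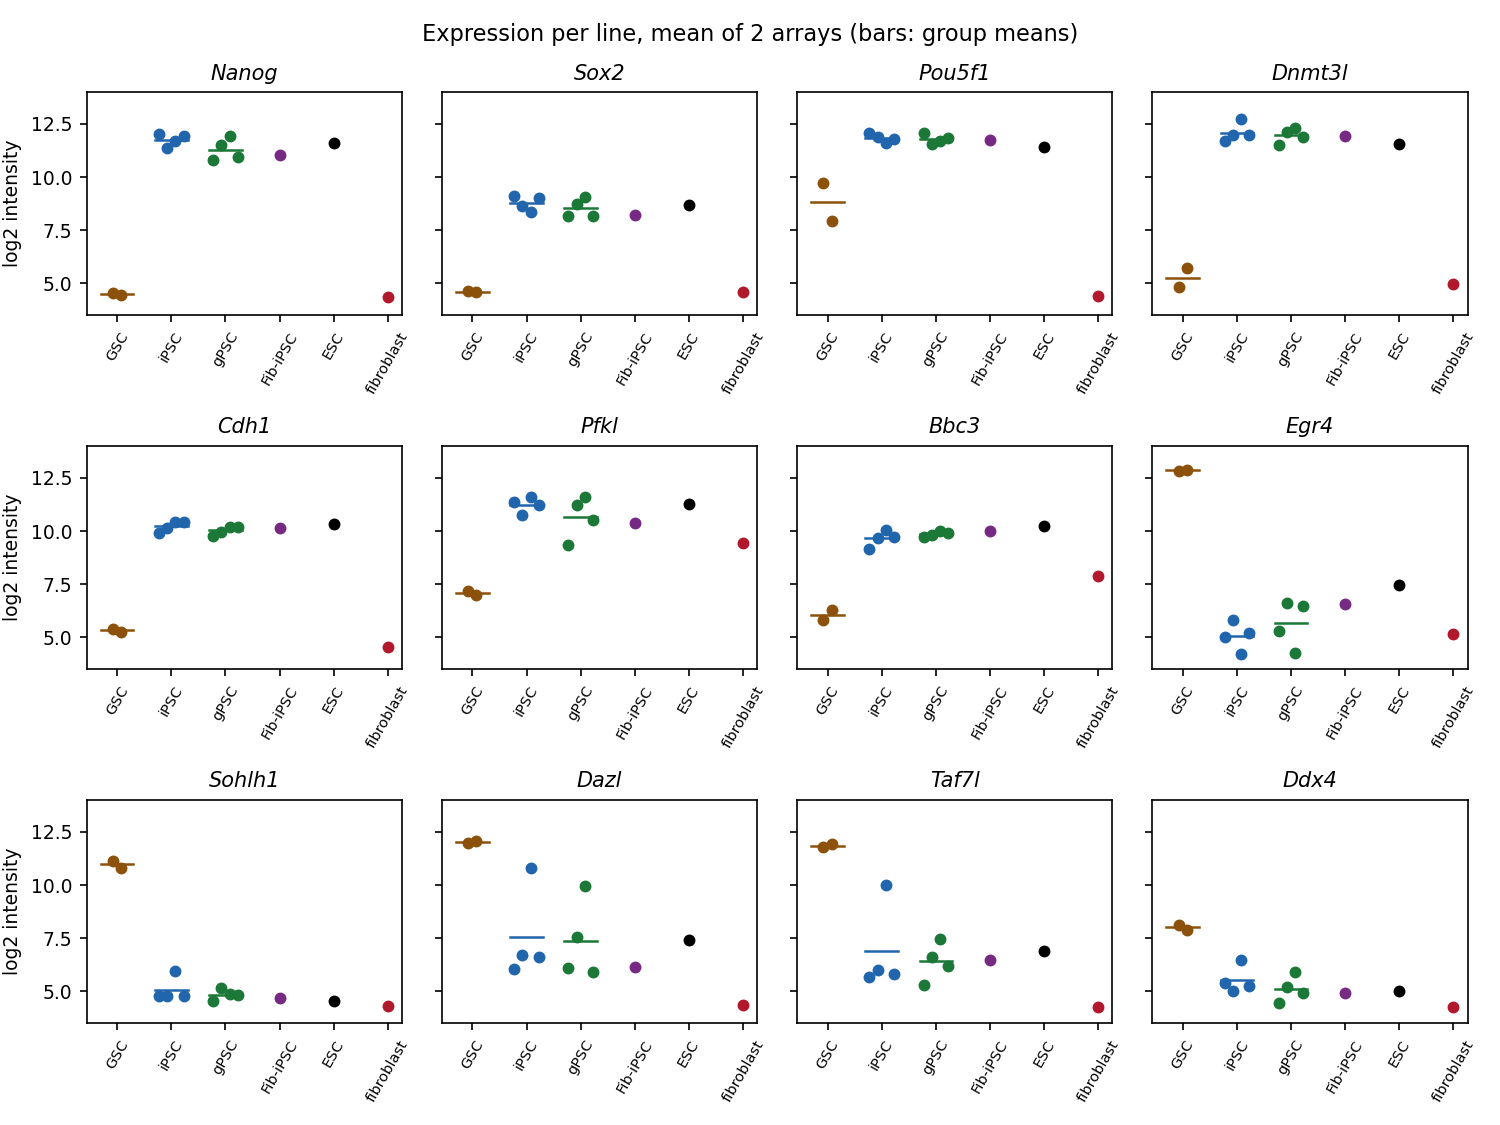
Log2 intensity of 12 genes (vertical axis) in each line, the mean of its 2 arrays, by group (horizontal axis); bars are group means. Nanog, Sox2 and Dnmt3l are low in GSC and fibroblast and high in every pluripotent line, and Dazl and Taf7l are high in GSC and, among iPSC lines, in iPSC 3 (10.8 and 10).

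The gPSC lines changed in much the same way. Nanog rose by 6.80 ± 0.31 (SE, 4 lines against 2, adjusted p = 7e-07), Sox2 by 3.93 ± 0.29, Pou5f1 by 2.94 ± 0.40 (2.04 to 3.84 when single lines were left out), Dnmt3l by 6.68 ± 0.34 and L1td1 by 6.57 ± 0.32. Egr4 (-7.20 ± 0.65), Mageb4 (-6.79 ± 0.71), Sohlh1 (-6.13 ± 0.33) and Tdrkh, a piRNA pathway gene (-5.12 ± 0.34), fell. With GSC values raised to the floor, Nanog (detected on 1 of 4 GSC arrays) rose by 6.67, L1td1 (1) by 6.52 and Sox2 (2) by 3.91. Of the 8 gPSC arrays, Tdrkh was detected on 5, Egr4 and Sohlh1 on 6 and Mageb4 on 7. Of the pluripotency network 19 of 29 genes rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 1.91e-11, and adjusted p = 0.0396 with an estimated correlation, or 0.0508 without gPSC 1). Of the germline list 28 of 34 fell and 2 rose (29 and 2 adjusted over the list alone; camera adjusted p = 1.91e-11, and adjusted p = 0.0917 with an estimated correlation). Limma called 2306 of 10660 genes, 1083 higher and 1223 lower in gPSC; 932 of these, and no others, were called with log2 quantile normalization. Dazl was lower by -4.64 ± 1.41 (adjusted p = 0.0254), but not without GSC 1, GSC 2, gPSC 1 or gPSC 4 (adjusted p up to 0.122), and was at 9.94 in gPSC 3. Klf4 was not called (0.50 ± 0.33, adjusted p = 0.257).

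Among the other lists, 11 of 19 glycolysis genes rose and 1 fell (12 and 1 adjusted over the list alone; Pfkl 3.57 ± 0.53, Ldha 3.01 ± 0.24; camera adjusted p = 4.48e-05, and adjusted p = 0.627 with an estimated correlation). In the p53 list 9 of 16 p53 targets rose (Bbc3 3.80 ± 0.24, Zmat3 3.66 ± 0.19; camera adjusted p = 3.16e-05, and adjusted p = 0.135 with an estimated correlation). Zscan4c was at least 21.5-fold higher, with 6 of 11 two-cell-like genes higher and 1 lower. Meiosis genes had 0 of 17 higher and 6 lower, among them Sycp1 (-2.34 ± 0.40, detected on 5 of 8 gPSC arrays). Mesenchymal genes had 3 of 33 higher, led by Ccn2 (3.59 ± 0.22). Camera gave adjusted p = 0.0432 for each of these 3 lists, but adjusted p = 0.627, 0.627 and 0.702 with an estimated correlation, and without gPSC 1 their camera values were adjusted p = 0.0766, 0.0809 and 0.313. That line stood apart on mesenchymal genes, with a list mean of 8.33 against 5.96 to 7.19 in the other iPSC and gPSC lines and 9.86 in the fibroblast line. The epithelial list had 4 of 17 genes higher and 3 lower (0.0949), Cdh1 at 4.71 ± 0.18. The paternally expressed list had 4 of 15 higher and 4 lower (0.814), Snrpn at 3.14 ± 0.21. Camera did not call the maternally expressed (2 higher and 3 lower of 12, 0.856), priming (3 and 1 of 23, 0.377), chromatin (5 and 2 of 23, 0.0542), oxidative phosphorylation (1 and 0 of 26, 0.41), sex-linked (0 and 1 of 4, 0.271) or testis somatic lists (2 and 1 of 9, 0.377).

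The genes called against GSC were largely shared between routes: 943 were higher in both iPSC and gPSC and 1062 lower in both, with 0 called in opposite directions. Independent lists of these sizes would share 121 and 143. In simulations of unchanged groups that kept the shared GSC lines, the mean overlap was 0 and 0.01 genes. Unchanged groups give almost no calls, so these simulations cannot show how far shared GSC lines raise the overlap of long lists. With a separate GSC line for each comparison (chosen after the data were seen), 737 were higher and 856 lower in both with GSC 1 for iPSC, and 752 and 838 with GSC 2 for iPSC. Independent lists of these sizes would share 79.2 and 112, and 81.8 and 109. The spread of these fits is still pooled over the lines.

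Between the iPSC and gPSC lines no gene was called by limma on line means. On the 26 arrays with line as a random block 3 genes, chosen after their values were seen, were called: Stard8 (1.69, adjusted p = 0.00508), Gprc5a (1.28, adjusted p = 0.0336) and Dpp4 (-1.17, adjusted p = 0.0336). On line means these had adjusted p = 0.597, 0.597 and 0.627. Stard8 alone was also called with an array-set term (1.73, adjusted p = 0.00691) and was at 6.64 to 7.83 in the iPSC lines against 4.95 to 6.35 in the gPSC lines. Among 10660 genes, 830 had an unadjusted p under 0.05, where 533 would be expected of unchanged genes, and 158 differed at least 2-fold. The pluripotency factors were close: Nanog differed by 0.47 ± 0.25 (SE, 4 lines against 4, adjusted p = 0.627), Sox2 by 0.24 ± 0.24, Pou5f1 by 0.06 ± 0.32 and Klf4 by 0.58 ± 0.27. The germline genes Ddx4 (0.40 ± 0.36) and Dazl (0.17 ± 1.15) were not called either. Leaving out single lines gave 0.30 to 0.69 for Nanog (lowest without gPSC 1), 0.11 to 0.42 for Sox2 (without gPSC 4 and gPSC 3) and 0.09 to 0.67 for Ddx4 (without iPSC 3 and gPSC 3). None was called. The direction of Pou5f1 turned without iPSC 1 or gPSC 2 (lowest -0.02), and that of Dazl without iPSC 3, gPSC 1 or gPSC 4 (lowest -0.92). On line means Iapp alone had an adjusted p under 0.05 (adjusted p = 0.0111). It was at least 1.65-fold lower in iPSC, detected on 0 of 8 iPSC and 4 of 8 gPSC arrays, and on the b arrays alone it was at -0.13 (adjusted p = 0.73). When the group means were made equal and 4-fold changes added to 200 genes of the iPSC lines, limma called 97% of them. Of added 2-fold changes it called 43%, so that 2-fold differences were detectable only in part. An adjusted p under 0.05 is easier to reach with 200 changed genes than with few. These shares are therefore too high where few genes differ. Tdgf1, detected on 4 of 8 gPSC arrays, differed by 3.06 and was not called.

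Between the iPSC and gPSC lines camera called 4 gene lists at the preset correlation, but 0 with an estimated correlation. Of 33 mesenchymal genes 28 were lower in iPSC than in gPSC (median -0.59, 0 called, camera adjusted p = 0.000231), with Zeb1, a repressor of epithelial genes, at -0.49 ± 0.14 (adjusted p = 0.627). Of 17 epithelial genes 15 were higher (median 0.42, camera adjusted p = 0.000343), with Cldn4 at 1.11 ± 0.32. Of 11 two-cell-like genes 10 were higher (median 0.53, camera adjusted p = 0.00947), with Tmem92 at 1.22 ± 0.45, and of 19 glycolysis genes 18 were higher (median 0.29, camera adjusted p = 0.00334). Adjusted over the list alone, 0 members of each passed, and with an estimated correlation each had adjusted p = 0.821. Fry called 0 lists here and 0 against ESC, but 10 of 15 for iPSC versus GSC, 10 for gPSC versus GSC and 7 for GSC versus ESC. These include chromatin genes (fry adjusted p = 0.00013, 0.000167 and 0.00287), which camera did not call. Most of this rested on single lines. Without gPSC 1, whose mesenchymal list mean was 8.33, camera gave adjusted p = 0.207 for mesenchymal genes and 0.472 for glycolysis. Glycolysis was not called without iPSC 3 either (0.0595), and two-cell-like genes were not called without iPSC 1 (0.0742), iPSC 2 (0.217) or gPSC 2 (0.194). The epithelial list kept its camera call without each of the 8 lines in turn (adjusted p up to 0.0273, without iPSC 3), but with an estimated correlation it had adjusted p from 0.628 to 0.92 in these fits. Its list mean was high in iPSC 3 (7.93) and iPSC 4 (7.51), while iPSC 1 (6.69) and iPSC 2 (6.54) lay below gPSC 3 (7.14) and gPSC 4 (6.74). The germline list (median 0.01, adjusted p = 0.98), pluripotency (0.16, adjusted p = 0.184, or 0.0111 without iPSC 3 and 0.237 there with an estimated correlation), maternally expressed (0.26, adjusted p = 0.379) and paternally expressed genes (-0.04, adjusted p = 0.52) were not called, nor were the remaining lists, with camera adjusted p from 0.428 to 0.949. Priming genes had a median and a mean above 0 (0.01 and 0.03) while their camera direction was down.

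Source-cell expression was measured with 247 germline signature genes, at least 4-fold higher in GSC than in ESC. These genes had to be called in a fit whose spread is pooled over lines, the iPSC and gPSC lines included. A germline gene kept high in only some of these lines has a larger spread and is more easily left out. This can pull the shares toward the ESC level. The genes were also chosen as low in the 1 ESC line that sets 0%, which can raise the share of any other line. The iPSC lines retained 1.87% ± 3.46 of the GSC level over ESC (SD, n = 4) and the gPSC lines 3.86% ± 1.28 (SD, n = 4), against 2.17% in Fib-iPSC, which the labels give as made from fibroblasts. Its profile was nearly that of gPSC 4 (root mean square difference 0.1516), so it serves as a background without germline origin only if its label holds. When single lines were left out, the share of Fib-iPSC ran from 2.04% (without gPSC 3) to 4.51% (without GSC 2). Without GSC 2 the shares of iPSC and gPSC were 2.22% and 4.70%. Sign and size depended on the scaling: the shares were -2.37% in iPSC, -0.42% in gPSC and -1.04% in Fib-iPSC with log2 quantile normalization, and 5.20%, 6.96% and 5.95% with the authors' values. The difference of -1.99 points between iPSC and gPSC was not significant (two-sided exact permutation p = 0.286, 0.685 adjusted over 8 measures). On the b arrays alone the shares were 3.46% in iPSC, 4.58% in gPSC and 2.52% in Fib-iPSC. The difference between iPSC and gPSC was -1.12 points there (exact permutation p = 0.6). iPSC 3, the line with high Dazl and Taf7l, had the highest share (6.80%) and iPSC 1 and iPSC 4 lay below ESC (-0.42% and -0.65%). Without iPSC 3 the iPSC mean was 0.109% and the difference -3.785 points (exact permutation p = 0.0286, unadjusted and the smallest that 35 assignments can give), while leaving out any other line gave -2.484 to -1.476 (exact permutation p from 0.171 to 0.457). With a signature of genes higher in GSC than in Fib-iPSC the difference turned to 2.97 points (exact permutation p = 0.6). The shares there were -3.95% in iPSC, -6.92% in gPSC and -13.93% in Fib-iPSC, so their sign also depended on the line chosen as low. Over the 402 genes at least 4-fold higher in ESC than in GSC, the shortfall from ESC, in percent of that of GSC, was 7.33 ± 2.34 in iPSC and 12.4 ± 5.03 in gPSC (exact permutation p = 0.114, adjusted 0.685). It was 11.2 in Fib-iPSC, so if the label of that line holds, it does not by itself mark a germline source.

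**Figure D3:**
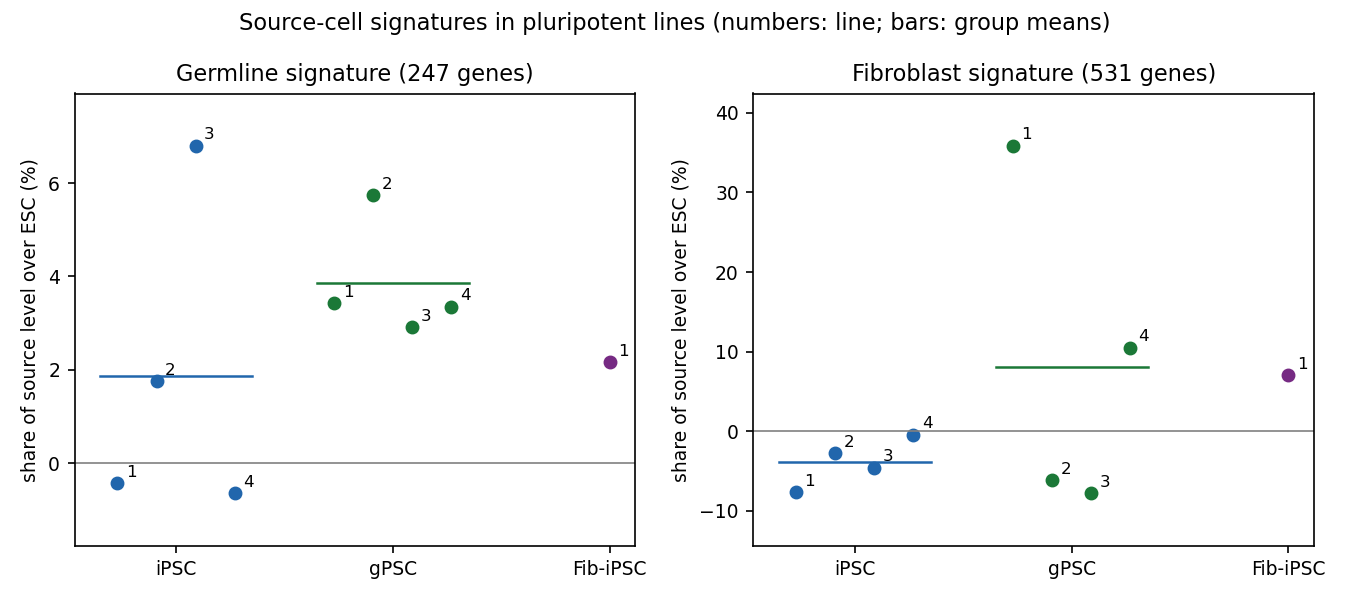
Retained share of the germline signature (247 genes, left) and of the fibroblast signature (531 genes, right), in percent of the source cell's level over ESC (vertical axis), for each iPSC, gPSC and Fib-iPSC line (points with line numbers; bars are group means). Germline shares run from -0.65% to 6.80%, and gPSC 1 has a fibroblast share of 35.9%.

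Few genes separated the pluripotent lines from ESC. Thumpd1, an RNA acetylation cofactor gene, was at least 13.6-fold lower in iPSC and at least 13-fold lower in gPSC (adjusted p = 3.05e-07 and 2.91e-07), and the ubiquitin ligase gene Trim59 was lower in iPSC (-3.62 ± 0.16) and gPSC (-3.47 ± 0.16). It was detected on 1 of 8 iPSC and 3 of 8 gPSC arrays, and with values raised to the floor it was at -3.45 and -3.31. Abhd16a, a lipase gene (-2.26 ± 0.13 and -2.09 ± 0.13), Csrp1, a cytoskeletal LIM protein gene (-2.61 ± 0.26 and -2.94 ± 0.26), and Hecw2 (at least 2.86-fold and 2.73-fold lower) were also lower in both. Abhd16a was detected on 2 of 8 iPSC and 4 of 8 gPSC arrays (-2.15 and -2.05 with values raised to the floor) and Csrp1 on 7 and 4 (-2.60 and -2.88). Such low levels were not particular to the pluripotent lines. Over the 10 GSC, iPSC and gPSC lines Thumpd1 ran from 4.20 to 4.31 and Trim59 from 4.36 to 4.77. Abhd16a ran from 4.44 to 4.78 there and Csrp1 from 4.37 to 5.52. Fib-iPSC lay within each of these ranges, while ESC and fibroblast lay above them. Ipp was higher in iPSC (3.29 ± 0.47, adjusted p = 0.0273) and in gPSC (3.68 ± 0.47, adjusted p = 0.0137), and so was Twistnb (2.49 ± 0.29 and 2.66 ± 0.29). Without iPSC 1 neither was called in iPSC (adjusted p = 0.0711 and 0.0502). Ipp was not called in iPSC without GSC 1, GSC 2, iPSC 3, iPSC 4 or gPSC 2 either (adjusted p up to 0.0711). Limma called 24 genes for iPSC (4 higher and 20 lower) and 26 for gPSC (3 higher and 23 lower). Of these, 3 were higher and 17 lower in both, where independent lists would share 0.00113 and 0.0432. In simulations of unchanged groups that kept the shared ESC line, the mean overlap was 0 and 0.01 genes. With almost no calls in unchanged groups, this cannot show how far the shared ESC line raises the overlap. Part of the excess may come from the ESC line, which is single and cannot be split between the comparisons.

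Core factors were not called against ESC: Nanog was at 0.14 ± 0.40 in iPSC and -0.33 ± 0.40 in gPSC, and Pou5f1 at 0.42 ± 0.51 and 0.36 ± 0.51 (adjusted p = 0.979 to 0.999). Only 20% and 26% of simulated 2-fold changes were recovered in these comparisons, so such differences are not excluded. Zfp42, not called either, ran from -1.24 to -0.92 in iPSC and from -1.87 to -1.41 in gPSC when single lines were left out. Two-cell-like genes were above ESC in 11 of 11 cases in both (median 1.03 in iPSC, camera adjusted p = 2.63e-06; 0.50 in gPSC, adjusted p = 0.0102; 0.60 in Fib-iPSC), with Tcstv1 at 2.47 ± 0.69 in iPSC (adjusted p = 0.533). Mesenchymal genes were lower in iPSC (28 of 33, camera adjusted p = 0.0124), and in gPSC epithelial genes (15 of 17, camera adjusted p = 0.00843) and maternally expressed genes (8 of 12, camera adjusted p = 0.0451) were lower. None of these kept its call with an estimated correlation (adjusted p = 0.924 and 0.985 in iPSC, 0.805 in gPSC). No member was called, and the epithelial values include gPSC 1. Among maternally expressed genes Grb10, a growth factor receptor adaptor, was at -2.49 ± 0.60 in iPSC and -1.47 ± 0.60 in gPSC, and Phlda2, a placental growth regulator, at -1.40 ± 0.49 and -1.77 ± 0.49 (adjusted p = 0.334 to 0.814). The remaining lists had camera adjusted p from 0.181 to 0.95 in iPSC and from 0.0653 to 0.923 in gPSC. With 1 ESC line the counts rest on a spread borrowed from other groups: with only the groups compared in the fit they were 2 and 3, and without iPSC 1 the iPSC count was 8.

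Mageb4 (7.03 ± 1.00), Sohlh1 (6.45 ± 0.47) and Tdrkh (5.29 ± 0.48, SE, 2 lines against 1) were higher in GSC, and Nanog (-7.13 ± 0.44), Dnmt3l (-6.30 ± 0.48) and Esrrb, an orphan nuclear receptor of the pluripotency network (-5.74 ± 0.45), were lower. With values raised to the floor, Nanog (detected on 1 of 4 GSC arrays) was at -7.00 and Sohlh1 (1 of 2 ESC arrays) at 6.34. Limma called 2187 genes, 1120 higher and 1067 lower in GSC (960 with log2 quantile normalization). Germline genes were higher (23 of 34, 2 lower; 24 and 2 adjusted over the list alone; camera adjusted p = 2.4e-10, and adjusted p = 0.117 with an estimated correlation) and pluripotency genes lower (18 of 29, 1 higher; 20 and 1 adjusted over the list alone; camera adjusted p = 3.03e-12, and adjusted p = 0.0307 with an estimated correlation). Glycolysis (11 of 19 lower, Ldha -3.41 ± 0.34; 5.83e-06) and p53 targets (9 of 16 lower, Bbc3 -4.18 ± 0.33; 9.05e-05) were lower, as were epithelial genes (5 of 17 lower and 1 higher, 0.0123). With an estimated correlation these had adjusted p = 0.646, 0.176 and 0.657. The other lists were not called (camera adjusted p from 0.0975 to 0.512). Klf4 was not called (-1.31 ± 0.47, adjusted p = 0.0635), but was without iPSC 1 or iPSC 3 in the fit (adjusted p down to 0.0307).

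**Figure D4:**
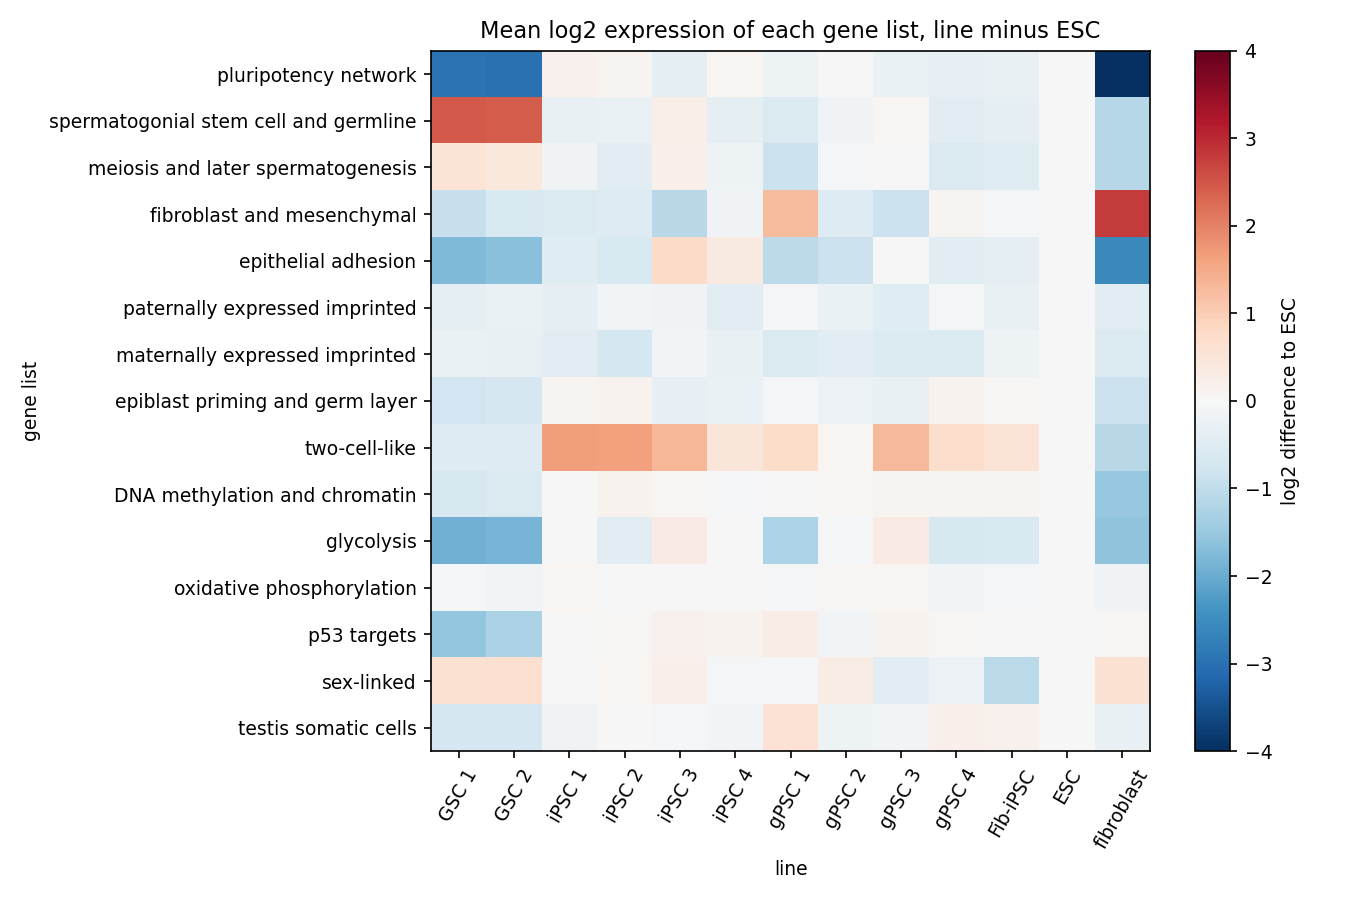
Mean log2 expression of each of 15 gene lists (vertical axis) in each line (horizontal axis), as the difference to the ESC line (colour scale, log2 units). The pluripotency network is low in GSC and fibroblast, the germline list is high in GSC, and the mesenchymal list is high in fibroblast (list mean 9.86) and gPSC 1 (8.33) against 7.08 in ESC.

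Fib-iPSC was compared with ESC and with its source cell type as single lines, without a test. Against fibroblast, 1664 genes were at least 2-fold higher and 1590 lower: the pluripotency genes Dppa5a and Sall4 were at least 440-fold and 138-fold higher, Pou5f1 at least 122-fold, and Esrrb at least 100-fold. The smooth muscle actin gene Actg2 was at least 131-fold lower and the collagen gene Col1a1 lower by -5.16. Of the pluripotency list 24 of 29 genes were at least 2-fold higher (median 3.83), and of the mesenchymal list 29 of 33 were at least 2-fold lower (median -3.03). Against ESC, 254 genes were at least 2-fold higher and 285 lower, among them the acute-phase gene Lcn2 (10.29 against 6.79) and the chemokine gene Cxcl5 (higher by 3.22, detected on 1 of 2 ESC arrays). Among 10000 matched lists each, the list medians against ESC lay at percentile 0 for glycolysis (-0.57), 0.16 for the germline list (-0.25), 1.13 for meiosis (-0.19), 1.42 for epithelial (-0.28), 2.8 for maternally (-0.23) and 2.88 for paternally expressed genes (-0.22), and 100 for two-cell-like genes (0.60). The other 8 lists lay at 9.21 to 92.3. With 1 line on each side these places do not separate the cell type from the line. The Y-linked Eif2s3y (4.30 against 8.35, at least 12.7-fold lower) and Erdr1 (4.42 against 9.29, at least 24.5-fold lower) were at the floor in Fib-iPSC. Fib-iPSC retained 7.06% of the fibroblast signature (531 genes), within the range of the 8 iPSC and gPSC lines (-7.82% to 35.9%), whose upper end is gPSC 1 alone (next gPSC 4, 10.5%). Lcn2 was at 4.27 in fibroblast but at 13.14 in gPSC 1 and 10.89 in gPSC 4, so its level in Fib-iPSC is no trace of the profiled fibroblasts.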

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

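The tests of leftover germline cells and of a pattern shared with gPSC 3, and those of the array set for Iapp, were chosen after the results were seen; the count of splits was planned.

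Among named genes and per-line measures, 302 groups of 4 lines were tested for a single line far from the other 3 (Dixon's ratio), of which 28 passed where chance flags about 1 in 20 groups, or 15.1. The tests are not independent, since a line that differs in many genes is counted at each.

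Some germline genes were high in 1 iPSC line, iPSC 3: of 247 signature genes 40 had a share of at least 10% of the GSC level and 99 a share of 0 or less. Its gap to the nearest other iPSC line, as a share of the range, was 0.865 for Dazl (10.8 against 6.07 to 6.71), 0.929 for Taf7l, 0.982 for Sohlh1 (5.97 against 4.77 to 4.79), 0.899 for Sycp1, 0.903 for Tex101, 0.84 for Tktl1 and 0.989 for the median share of the germline signature. Leftover germline stem cells would bring all GSC transcripts alike. The median share of the GSC level over 247 signature genes was 0.876%, against 41.4% for Dazl and 26.6% for Taf7l. Genes raised in iPSC 3 are more easily left out of this signature, which can lower that median. Leftover cells at the shares of Dazl and Taf7l would still not leave 99 of the 247 genes at 0 or less. The values argue against such cells as the source of the Dazl and Taf7l levels, not against a smaller share of them. A pattern shared with gPSC 3 stays open: of 21 genes raised at least 4-fold in iPSC 3, 3 are in the germline signature and 95.2% were highest in gPSC 3 among gPSC lines, where 25% would be expected, and Dazl was at 9.94 there. The germline signature did not show this sharing: gPSC 3 had the lowest germline share of the gPSC lines (2.92% against 3.36% to 5.75%). Genes raised in only iPSC 3 and gPSC 3 are more easily left out of that signature. The germline list mean was highest in gPSC 3 among gPSC lines (6.147 against 5.514 to 5.924). Among iPSC lines it was highest in iPSC 3 (6.354 against 5.675 to 5.826). The meiosis list gave the same order (gPSC 3 6.035 against 5.151 to 5.926, iPSC 3 6.203 against 5.586 to 5.864). The 25% treats the 21 genes as independent, while the deviations of iPSC 3 and gPSC 3 correlated at 0.678 across genes. The pattern of these 21 genes may belong to a state that lines of both routes can enter. This is a hypothesis found and tested on the same data, and no biological explanation from the design was tested.

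Other genes in iPSC 3 stood apart singly: the Y-linked Eif2s3y was higher (0.83), Inha lower (0.837) and Ldha higher (0.984, 13.04 against 12.8 in the others). iPSC 4 was low for Bmi1 (0.839), Inpp5f (0.89), Rhox5 (0.908, 10.68 against 12.0 to 12.14), Tcstv1 (0.842) and Tdrkh (0.88). iPSC 2 was low for Aldoc (0.947, 7.63 against 9.48 to 9.58), Ccna1 (0.902), Hspa2 (0.934) and Zfp42 (0.873, 8.18 against 9.02 to 9.15), and high for Ring1 (0.941) and Trim59 (0.906, 4.64 against 4.36 to 4.38). Among gPSC lines, gPSC 3 was low for Trh (0.873, 6.64 against 11.26 to 11.94), Spint1 (0.902) and Uty (0.838) and high for Stra8 (0.842). The line gPSC 2 lay above the other gPSC lines for the Y-linked Eif2s3y (0.89, 8.99 against 7.02 to 7.24) and Kdm5d (0.882), and gPSC 1 for Cer1 (0.901). For Eif2s3y gPSC 1, gPSC 3 and gPSC 4 were the low ones. It was at 8.98 and 9.01 in GSC, 8.26 to 9.31 in iPSC, 8.35 in ESC and 8.96 in fibroblast. Dixon's ratio takes no account of the size of a gap, which was small for Ldha and Ring1 (6.96 against 6.69 to 6.71). Some values of Inha, Bmi1, Tdrkh, Ccna1, Trim59, Stra8, Kdm5d and Cer1 lay within or below the range of the array floors (4.56 to 4.81). So did Sohlh1, Sycp1, Tex101 and Tktl1 in the iPSC lines other than iPSC 3, so that their ratios rest on signals near background.

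Iapp was the gene whose change from GSC differed between iPSC and gPSC (log2 difference -0.93, adjusted p = 0.0111), but it was detected on 0 of 8 iPSC arrays, which makes that difference a bound (at least 1.65-fold). On the b arrays alone the difference was -0.13 (adjusted p = 0.73), and on the 26 arrays, with line as a random block and a term for the array set, it was -0.19 (adjusted p = 0.861). The difference thus lay in the a arrays of the GSC, gPSC, ESC and Fib-iPSC lines.

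For iPSC versus gPSC, limma called 0 genes (830 at an unadjusted p under 0.05). All 35 of the 35 splits of the 8 lines gave at least as many calls, which a count of 0 fixes beforehand, so that this count decides nothing. At an unadjusted p under 0.05, 11 of the 35 splits, the real one included, gave at least as many genes as the real one. The highest other count of calls was 382, from the split of iPSC 1, 3, 4 and gPSC 3 against iPSC 2 and gPSC 1, 2, 4, which points to a structure of the lines that crosses the groups.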

How the results depend on the processing

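Alternatives chosen after the data were seen were the b arrays alone, the array-set term, values raised to the floor, separate GSC lines in the overlap of calls and leaving out lines from the list tests (each iPSC and gPSC line for iPSC versus gPSC, gPSC 1 alone against GSC, none against ESC). Where a value changed, the cause was not tested. Log2 quantile normalization without background correction called 1023 genes for iPSC versus GSC and 932 for gPSC versus GSC. Against ESC it called 10 for iPSC, 8 for gPSC and 960 for GSC. Of the genes called by default, 0 were called in the opposite direction. The retained germline share became -2.372% in iPSC and -0.4167% in gPSC, and the fibroblast share of Fib-iPSC 2.361%. The authors' processed values called 1 gene for iPSC versus gPSC and 17 for gPSC versus ESC, and gave germline shares of 6.956% in gPSC, 5.2% in iPSC and 5.954% in Fib-iPSC. Without a fold threshold 4708, 4516 and 1 genes were called for iPSC versus GSC, gPSC versus GSC and iPSC versus gPSC. The 26 arrays with line as a random block called 3 genes for iPSC versus gPSC, 60 for iPSC versus ESC and 61 for gPSC versus ESC; the array-set term added to that fit called 1, 49 and 55; and only the groups compared called 2 for iPSC versus ESC and 3 for gPSC versus ESC.

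The gPSC germline share was 5.757% with a 2-fold signature (iPSC 3.72%, Fib-iPSC 5.163%) and 2.505% as a median over genes. With the signature of GSC over Fib-iPSC, the shares were -3.953% in iPSC and -6.921% in gPSC, and their difference reversed to 2.968. Leaving out each line in turn gave -3.785 to -1.476 for that difference (without iPSC 3 and iPSC 1), 8 to 23 genes for iPSC versus ESC (without iPSC 1 and gPSC 1), and -0.008183 to 0.0374 for the difference in distance to GSC (without gPSC 2 and gPSC 1). For iPSC versus gPSC it gave -0.023 to 0.146 for Pou5f1 (reversed without iPSC 1 or gPSC 2) and -0.917 to 1.019 for Dazl (reversed without iPSC 3, gPSC 1 or gPSC 4). For Igf2 in iPSC versus GSC, not called, it gave -0.446 to 0.107 (reversed without GSC 2 or iPSC 2). Of 27 gene list calls, 3 were kept with an estimated correlation, and of 4 for iPSC versus gPSC, leaving out a line gave 2 to 4 (2 without gPSC 1).

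Lines of the same number are not pairs by the labels; their deviations correlated at -0.0665, -0.0679, 0.678 and -0.0662, and with line number as a block limma called 0 genes and camera 4 lists. Named called genes kept direction and call in 3852 of 4122 values over all alternatives, lost the call in 270 and reversed in 0. Signals near the array floor limit what can be measured of weakly expressed genes.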

Other observations

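The tests of mesenchymal genes in gPSC 1 and of Phlda2 and Grb10 below were chosen after the results were seen. The gPSC 4 and Fib-iPSC lines, which the labels give different sources, were closer to each other than any other pair of lines: their log2 profiles differed by a root mean square of 0.1516 (r = 0.9974), the next closest pair being GSC 1 and GSC 2 at 0.2261. Array by array they differed by 0.1913 to 0.2178, within the 0.1638 to 0.2229 between the 2 arrays of a single line. A gene was taken to part 2 sets of arrays where all arrays of one lay at least 2-fold above all arrays of the other. By this measure 9 genes parted these lines, against 1 gene parting their a from their b arrays. The 9 were the Y-linked Eif2s3y (7.24 in gPSC 4 and 4.30 in Fib-iPSC), Erdr1 (6.44 and 4.42), Grb10 (7.55 and 8.78), Phlda2 (8.46 and 9.58), Rhox9, Usp44, Msmo1, Hal and Zfp869. Whether the lines are related or a sample is mislabelled is not settled by these values. Results that rest on Fib-iPSC as a line of another origin hold only if its label and that of gPSC 4 are right. These are the background of the germline share and of the shortfall from ESC, the fibroblast share, and the reference for Phlda2 and Grb10. Were gPSC 4 the mislabelled line, every gPSC mean and test over 4 lines would include a line of another origin. Without it limma still called 0 genes for iPSC versus gPSC and 2222 for gPSC versus GSC, and the gPSC germline share was 4.207%.

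Some single genes, chosen after their values were seen, varied among pluripotent lines. Lefty1, a Nodal pathway inhibitor, was at 5.15 in iPSC 3 and 6.66 in gPSC 3, against 9.72 to 11.49 in the other iPSC and gPSC lines, and Lin28a at 6.77 and 7.01 against 8.11 to 9.35. The priming list did not part these 2 lines (means 5.73 and 5.76, against 5.80 in iPSC 4 and 5.81 in gPSC 2). Thumpd1 was at 4.20 to 4.31 in the 10 GSC, iPSC and gPSC lines and at 4.24 in Fib-iPSC, against 8.36 in ESC and 7.82 in fibroblast. Of 8 genes that part those 10 lines from ESC and fibroblast by a gap of at least 2-fold, Fib-iPSC lay within the range of the 10 lines at 7. For Tdgf1, the probe used read 4.28, 4.39 and 4.32 in gPSC 3, gPSC 4 and Fib-iPSC, where a dimmer probe of the gene read 6.78, 6.81 and 6.82.

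Mesenchymal and inflammatory genes were high in gPSC 1: 73 genes were raised at least 8-fold over the median of 6 other iPSC and gPSC lines, among them Lcn2 (13.14), Saa3 (12.85), Mmp3 (12.58), Dcn (11.68) and Lum (11.21). RNA of the profiled fibroblasts is argued against, since 47 of the 73 genes exceeded the level of the whole fibroblast line (Lcn2 4.27 and Saa3 4.61 there) while its abundant Actg2 (11.71) was at 5.13 in gPSC 1; the array set is argued against by a fibroblast signature of 36.0% on the b arrays and 35.9% on both. One cell population present at different shares stays open: the excess in gPSC 4 relative to gPSC 1 had a median log2 ratio of -2.15 and varied across the genes by an SD of 0.53; Fib-iPSC, whose profile nearly equals that of gPSC 4 and adds no independent evidence, gave -2.63 and 0.59, and iPSC 2, with 71 of the genes above that median, gave -4.2 and 1.51. Mesenchymal cells of another origin, such as feeder cells, may be the source, with a mesenchymal list mean of 8.33 in gPSC 1; the labels state neither feeders nor a sort that would remove them.

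Phlda2 and Grb10, 2 maternally expressed imprinted genes, were lower in all 8 iPSC and gPSC lines than in ESC and the line labelled Fib-iPSC (Phlda2 7.34 to 8.73 against 9.63 and 9.58, Grb10 6.10 to 8.63 against 9.01 and 8.78), and the GSC lines were also lower (Phlda2 8.23 and 7.98, Grb10 6.39 and 7.02). The array set is argued against, since on the b arrays Phlda2 differed by -1.52, and so is a paternal state at all imprinted genes, which would raise paternally expressed genes: their upper quartile was 0.11. Chance stays open: 2 of 12 listed genes were below where 0.153 would be expected, with a hypergeometric p of 0.294 after adjustment over lists and directions (136 of 10660 genes were below). Cdkn1c, another maternally expressed gene, did not follow Phlda2 and Grb10. It was at 9.32 in iPSC 3 and at 10.45 and 10.09 in GSC, above ESC (8.52) and Fib-iPSC (7.82). The remaining iPSC and gPSC lines (5.89 to 7.61) lay below both. The germline source of the 8 lines may bear on Phlda2 and Grb10 as a hypothesis, but with 1 ESC and 1 Fib-iPSC line it was not tested. Methylation of their control regions in these lines and further ESC lines would test it.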
